A study of Mus musculus with 20 samples.

How the data were processed

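RNA was profiled from subcutaneous tumours of MC38, a mouse colon adenocarcinoma line, in 20 libraries. Per the labels, 10 libraries came from vehicle-treated tumours (Control) and 10 from tumours given peri-tumoral ATBx (P.T.ATBx), and each library belonged to the group in its title. ATBx is a common abbreviation for antibiotic treatment, and the labels name no agent, dose or schedule. Per the labels' extract protocol, RNA was taken with a column kit and libraries were built with a stranded total RNA kit, which keeps non-polyadenylated transcripts. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples, which may be partly technical.

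The authors deposited 1 table of FPKM (fragments scaled to gene length and to the mapped fragments of the library), with 1 column per library and 23402 rows, each with an Entrez gene number and a symbol. The reference build was mm10 (GRCm38), per the submitters' processing notes. The aligner, the quantification tool and the gene annotation are not given in the sources used here. From the values, the upper quartile of FPKM differed by 1.05-fold at most between libraries while the summed FPKM ran from 556770 to 752782, so a further scaling between libraries could have been applied before the values were written. FPKM is not a count, and read totals are unknown. Low values are spaced by what 1 read is worth, and comparing that step between libraries gave a relative depth from 0.818 to 1.30, a 1.59-fold range. An exact 0 in the table can be a failed estimate: of 7042 rows with a median FPKM above 10, 17 were listed at 0 in some library, and 15 of these were small nuclear or nucleolar RNAs. Reads shared by near-identical copies cannot be told apart in such a table, so values of the granzyme cluster, Hspa1a, the Prl2c and H2-Q families and the clustered protocadherins are uncertain.

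Values were analysed as log2(FPKM + 1). Of the 23402 rows, 4814 were at 0 in every library, and the 12788 rows with a mean FPKM of at least 0.5 over all 20 libraries were tested. A linear model with group as its only term was fitted in limma 3.58.1 under R 4.3.3, with robust and trended moderation of the variances, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are P.T.ATBx minus Control on the log2(FPKM + 1) scale, which understates the change of low genes. The script was tested on simulated data with 50 genes changed at each fold size among 12788. It recovered 66% of the genes changed 1.25-fold, 92% at 1.5-fold, 96% at 2-fold and 96% at 4-fold, and 5 of its 180 calls were false. The simulation shuffled residuals gene by gene, which removes the correlation between genes and the structure of the libraries. Its share of false calls therefore need not hold for the real data.

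The design, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. There were 31 gene lists, covering interferon responses, sensing of nucleic acids and bacteria, inflammation, antigen presentation, immune and stromal cell types, neighbouring skin, muscle and fat, blood, and stress. The list of type 17 lymphocyte genes had 1 tested member and the list of mitochondrially encoded genes had 0 rows in the table, so 29 lists were tested. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with camera using an estimated correlation, and with fry, whose directional p asks whether a list's genes move one way on balance and whose mixed p asks whether they change in either direction. A list score, the mean over tested members of log2(FPKM + 1) centred per gene, was compared between groups by a two-sided permutation test with 100000 resamples, adjusted by Benjamini-Hochberg over the lists. Relations between list scores were computed within each group of 10 as Pearson's r and Spearman's rho with permutation p-values.

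Genes were named by this rule: the 10 genes with the largest absolute log2 fold change in each direction among those past the adjusted threshold, leaving out predicted genes and pseudogenes by name; up to 4 members with the smallest unadjusted p of each list described; and preset genes, among them Ifnb1, Ifng, Isg15, Irf7, Cxcl9, Cxcl10, Cd274, Cd8a, Gzmb, Tmem173, B2m, S100a8 and Il1b in any case. Any other gene is said to have been chosen after its values were seen. Coordinates and gene types came from an NCBI RefSeq table of GRCm38, in which 23324 of the Entrez numbers matched, and transcript length and GC content came from GENCODE M21, for 99.5% of the tested rows.

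The alternatives were a pseudocount of 0.1, no filter on low values, a filter at a mean FPKM of 1, quantile normalization, median-of-ratios scaling, rescaling to 1 sum per library (TPM scale), limma's arrayWeights, moderation without robust and trend, the replicate number as a block, covariates for skeletal muscle, keratinocyte and adipocyte scores, Ptprc as a covariate for leukocyte content in the interferon scores, and leaving out each library in turn. Added after seeing the data were the fit without 4 libraries that stand apart in composition (Control 1, Control 3, P.T.ATBx 1 and P.T.ATBx 4), the mean of 83 ribosomal protein genes as a covariate, Ptprc as a covariate in the gene counts, and the removal of each library's trend with transcript length and GC content. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.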

Results

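The data describe RNA levels in MC38 tumours grown under the skin of mice, 10 given vehicle (Control) and 10 given ATBx around the tumour (P.T.ATBx). The title of the study concerns the microbial burden of tumours and interferon signalling, so the comparison asks how tumour RNA, interferon-responsive genes in particular, differed after local ATBx. The table held 15527 to 16345 rows above 0 per library. Library composition varied within both groups: the RNA components of RNase P and RNase MRP, Rpph1 and Rmrp, took 7.75% to 20.5% of summed FPKM. Their share was 12.2% ± 3.6 in Control and 12.4% ± 2.4 in P.T.ATBx (SD, n = 10 each, two-sided permutation p = 0.904). Summed FPKM (p = 0.938), rows above 0 (p = 0.416), relative depth (p = 0.176) and the mean log2 level of ribosomal protein genes (p = 0.677) showed no difference past the threshold by the same permutation test.

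P.T.ATBx tumours carried less RNA of 3 granzyme genes, of the arginine-degrading enzyme Arg1 and of the tryptophan-degrading enzyme Ido1. They carried more RNA of the growth factor Igf2, the neighbouring noncoding RNA H19, the membrane glycoprotein Gpnmb and the coagulation initiator F3 (tissue factor). The granzymes, serine proteases of cytotoxic lymphocyte granules, made 3 of the 5 falls beyond 1 in log2 fold change. Gzmg fell from 7.86 ± 3.45 FPKM to 1.01 ± 0.629, Gzmd from 12.9 ± 5.78 to 2.63 ± 1.28 and Gzme from 4.85 ± 2.18 to 0.935 ± 0.571 (SD, n = 10 per group). Arg1 fell from 72.2 ± 43.6 to 18.8 ± 12.6 FPKM and Ido1 from 8.33 ± 3.75 to 3.28 ± 1.96. Igf2 rose from 0.962 ± 0.275 to 2.23 ± 0.260 FPKM, H19 from 43.9 ± 10.4 to 66.8 ± 13.5 and Gpnmb from 22.8 ± 3.03 to 44.2 ± 16.8.

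Of 12788 genes tested, 59 were higher and 49 lower after P.T.ATBx at an adjusted p under 0.05 (limma, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 1738 genes, where chance alone would give 639.4. Most changes were small, with a median absolute log2 fold change of 0.37 among the called genes, and beyond 1 in absolute log2 fold change there was 1 higher and 5 lower. In 17 of the 12788 genes tested, 9 higher and 8 lower, all 10 P.T.ATBx libraries lay beyond all 10 Control libraries, against 0.138 genes by chance. Not all of the 9 higher ones passed the adjusted threshold. The median log2 fold change of all genes was 0.00.

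Among the genes lower after P.T.ATBx, the 10 largest changes had these values. Gzmg had a log2 fold change of −2.09 (SE 0.22, adjusted p = 4.2e-05, limma), Gzmd −1.90 (SE 0.26, adjusted p = 0.000664, limma) and Gzme −1.56 (SE 0.21, adjusted p = 0.000609, limma). In each of these all P.T.ATBx libraries lay below all Control libraries. Arg1 had −1.97 (SE 0.35, adjusted p = 0.00622, limma) and Ido1 −1.16 (SE 0.25, adjusted p = 0.0310, limma). The endothelial lipase gene Lipg fell by 0.58 on the log2 scale (adjusted p = 0.000609, limma), with the groups fully apart. The remaining genes of the 10 were Prl2c2, a prolactin-family hormone gene with near-identical copies, at −0.72, the arylsulfatase gene Arsi at −0.70, Islr at −0.66 and Tmem26 at −0.60, with adjusted p (limma) from 0.000687 to 0.0115. On leaving out the 4 libraries that stand apart in composition, Prl2c2 lost its call (adjusted p = 0.11, limma). In each of these 10 genes, 9 or 10 of the 10 P.T.ATBx libraries lay below the Control median.

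The granzyme genes lie in a cluster on chromosome 14 (GRCm38), with Gzme at 56117619 to 56120625, Gzmd at 56129556 to 56132603 and Gzmg at 56156581 to 56159579. Their neighbours were looked at after these values were seen. Gzmf (56205263 to 56211407) had a log2 fold change of −1.14 (SE 0.34, p = 0.00318, adjusted p = 0.119, limma). Gzmc (56231397 to 56241647) had −0.02 (SE 0.34, adjusted p = 0.987, limma) at 124 FPKM in Control and 110 in P.T.ATBx. Gzmb, at the end of the cluster (56258836 to 56262334), had −0.20 (adjusted p = 0.780, limma), from −0.33 without Control 3 to −0.08 without P.T.ATBx 2, and Gzma on chromosome 13 had −0.37 (adjusted p = 0.389, limma). Gzmc to Gzmg are close copies of each other, so the split of reads among them is uncertain.

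**Figure D1:**
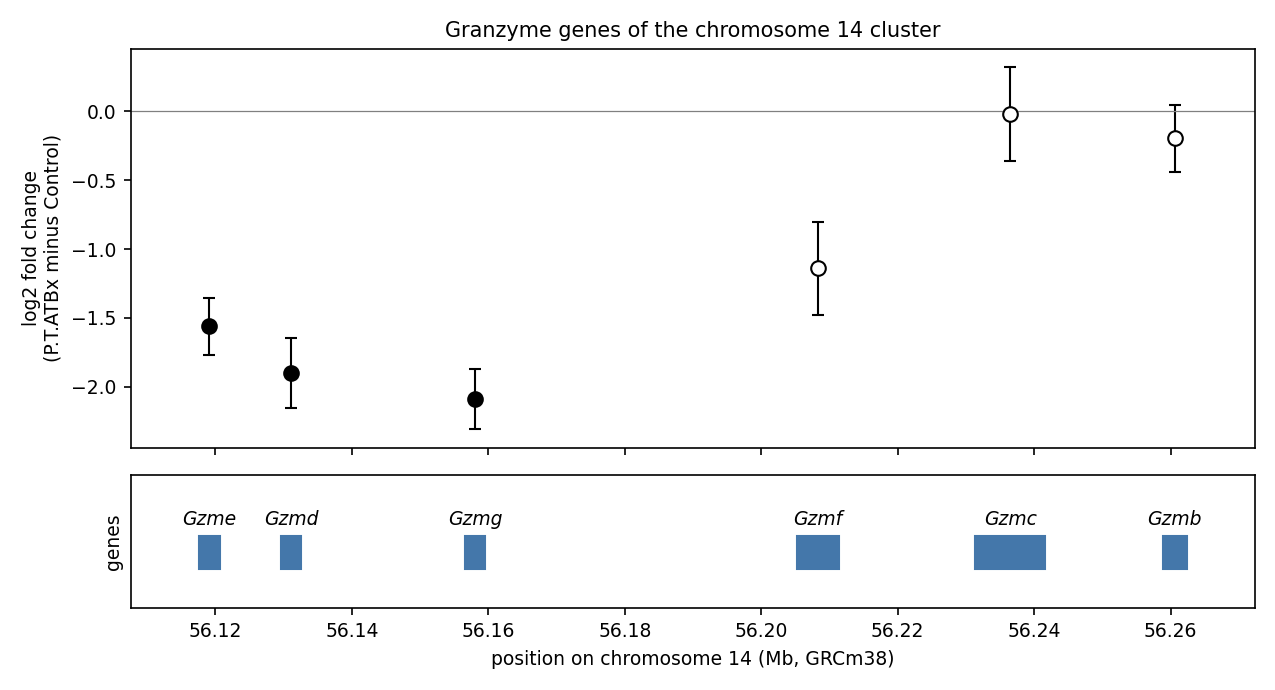
The upper panel plots the log2 fold change of each granzyme gene (P.T.ATBx minus Control, log2(FPKM + 1) scale, bars are 1 SE, n = 10 per group) against its position on chromosome 14 in Mb, with filled points for an adjusted p under 0.05; the lower panel draws the genes to scale. Gzme, Gzmd and Gzmg, with −1.56, −1.90 and −2.09, lie side by side, and Gzmc and Gzmb lie near 0.

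Among the genes higher after P.T.ATBx, Igf2 (chromosome 7, 142650768 to 142666816) rose by 0.73 on the log2 scale (SE 0.07, adjusted p = 2.83e-05, limma), with all P.T.ATBx libraries above all Control libraries. H19 (chromosome 7, 142575530 to 142578146), which shares an imprinted domain with Igf2, rose by 0.61 (SE 0.12, adjusted p = 0.0172, limma). The receptor tyrosine kinase gene Epha3 rose by 0.59 (adjusted p = 0.00031, limma), again with the groups fully apart. Gpnmb rose by 0.86 (adjusted p = 0.00622, limma), and F3 by 0.69 (adjusted p = 0.0017, limma). The synaptic vesicle gene Syngr1 rose by 0.64 (adjusted p = 0.0031, limma) and the immediate early transcription factor gene Fosb by 0.68 (adjusted p = 0.0108, limma). Ubl4a at 1.04, the matricellular protein gene Nov at 0.98 and the laminin receptor gene Itga7 at 0.53 completed the 10, with adjusted p (limma) of 0.0115, 0.0478 and 0.0316. Ubl4a was low, at a mean of 1.58 FPKM in Control and 4.16 in P.T.ATBx, with SE 0.20 for its log2 fold change. Ubl4a lost its call with a pseudocount of 0.1 (adjusted p = 0.0861, limma) and without the 4 libraries that stand apart (adjusted p = 0.112, limma), and H19 on the TPM scale (adjusted p = 0.0814, limma) and without those 4 (adjusted p = 0.11, limma). Nov lost its call in 17 fits and Itga7 in 11. Between 9 and 10 of the 10 P.T.ATBx libraries lay above the Control median for each of these genes.

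**Figure D2:**
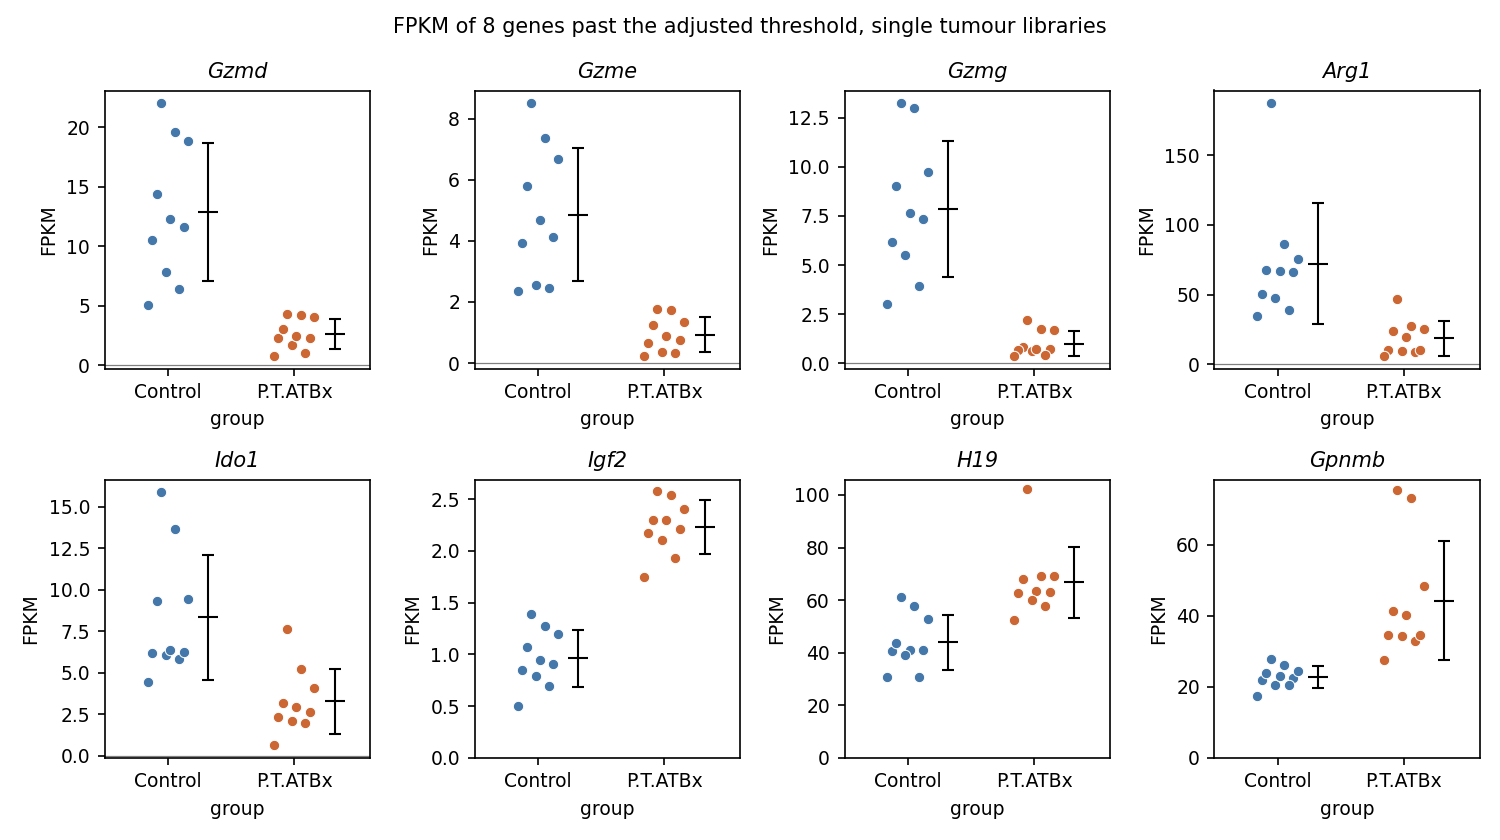
Each panel plots the FPKM of 1 gene on a linear axis from 0, with a point per tumour library in the Control and P.T.ATBx groups (n = 10 each) and the mean with its SD beside the points. Gzmd, Gzme, Gzmg and Igf2 do not overlap between the groups; Arg1, Ido1, H19 and Gpnmb overlap in part, with Arg1 means of 72.2 and 18.8 FPKM.

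After rescaling each library to 1 sum, 20 genes were higher and 29 lower, so the share of higher genes was 40.8% in place of 54.6%. Without the 4 libraries that stand apart in composition, 31 were higher and 36 lower, 55 of them among the genes called in all libraries. Leaving out Control 1 gave 104 higher and 89 lower, leaving out Control 2 gave 78 lower, and leaving out P.T.ATBx 4 gave 38 higher and 31 lower.

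Interferon-responsive genes had negative log2 fold changes almost without exception, most of them small. Of 38 type I interferon-stimulated genes, 37 had a negative log2 fold change, with a median of −0.17, and all 30 type II interferon response genes did, with a median of −0.36. Single genes of the type I list had modest values: the mitochondrial nucleotide kinase gene Cmpk2 fell from 11.7 ± 2.03 to 9.01 ± 1.66 FPKM by the test adjusted over the list alone. Isg15 (105 ± 27.0 and 93.6 ± 13.3 FPKM, SD, n = 10 each) and Irf7 (60.4 ± 10.7 and 55.6 ± 11.9) differed by less than the spread between libraries. Below the Control median lay 3 of the 10 P.T.ATBx libraries for Isg15 and 7 for Irf7.

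In the type I list, 0 of 38 members passed the adjusted threshold over all genes, and 2, Ifi27l1 (log2 fold change −0.30) and Cmpk2 (−0.34), were lower adjusted over the list alone. Stat2 (−0.37) and Bst2 (−0.22) had the next smallest p. The list was lower by camera (adjusted p = 3.55e-07), and this call was lost with adjusted p = 0.626 with an estimated correlation, which was 0.672 between its genes. Its score was 0.0903 ± 0.249 in Control and −0.0903 ± 0.241 in P.T.ATBx (SD, n = 10 each, two-sided permutation p = 0.116, adjusted p = 0.337), and 7 of 10 P.T.ATBx libraries lay below the Control median.

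In the type II list, 1 of 30 members was lower over all genes, Ido1, and 3 were lower adjusted over the list alone: Ido1, the cytokine signalling inhibitor Socs1 (log2 fold change −0.37) and the surface antigen Ly6a (−0.51). The immunity-related GTPase gene Iigp1 had −0.54 (adjusted p = 0.281, limma). The chemokine genes Cxcl9 (−0.38, adjusted p = 0.605, limma) and Cxcl10 (−0.41, adjusted p = 0.402, limma) and the ligand gene Cd274 (−0.32, adjusted p = 0.444, limma) did not pass. Cxcl9 ran from −0.505 without Control 2 to −0.254 without P.T.ATBx 2. The list was lower by camera (adjusted p = 7.59e-11), a call lost with adjusted p = 0.573 with an estimated correlation, which was 0.828. The score was 0.186 ± 0.395 in Control and −0.186 ± 0.411 in P.T.ATBx (SD, n = 10 each, two-sided permutation p = 0.0541, adjusted p = 0.224), with 9 of 10 P.T.ATBx libraries below the Control median. Ido1 lost its call on the TPM scale (adjusted p = 0.055, limma), without the 4 libraries that stand apart (adjusted p = 0.141, limma) and, with adjusted p from 0.0515 to 0.0649 (limma), without any 1 of Control 6, 9 or 10 or P.T.ATBx 1, 3, 4 or 10.

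The interferon genes themselves were low. Ifng, the type II interferon gene, was at 2.75 ± 1.28 FPKM in Control and 1.72 ± 0.664 in P.T.ATBx (SD, n = 10 each, log2 fold change −0.42, SE 0.19, p = 0.0434, adjusted p = 0.349, limma). Ifnb1 lay below the filter, with 0.146 ± 0.118 and 0.216 ± 0.173 FPKM, was listed at 0 in 3 Control and 1 P.T.ATBx libraries, and showed no difference past the threshold (two-sided permutation p = 0.328). Of 6 tested interferon ligand and receptor genes 0 passed, 4 had positive and 2 negative values, and the list median was 0.00 while its mean of −0.06 and its camera direction were negative (adjusted p = 0.808). Among 16 genes of cytosolic and endosomal nucleic acid sensing 0 passed over all genes, and adjusted over the list alone Tlr7, an RNA sensor, was higher (log2 fold change 0.24) and Mb21d1, which encodes the DNA sensor cGAS, lower (−0.17). Its adaptor Tmem173 (STING) had −0.10 (adjusted p = 0.610, limma), and the list was not called by camera (adjusted p = 0.377).

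**Figure D3:**
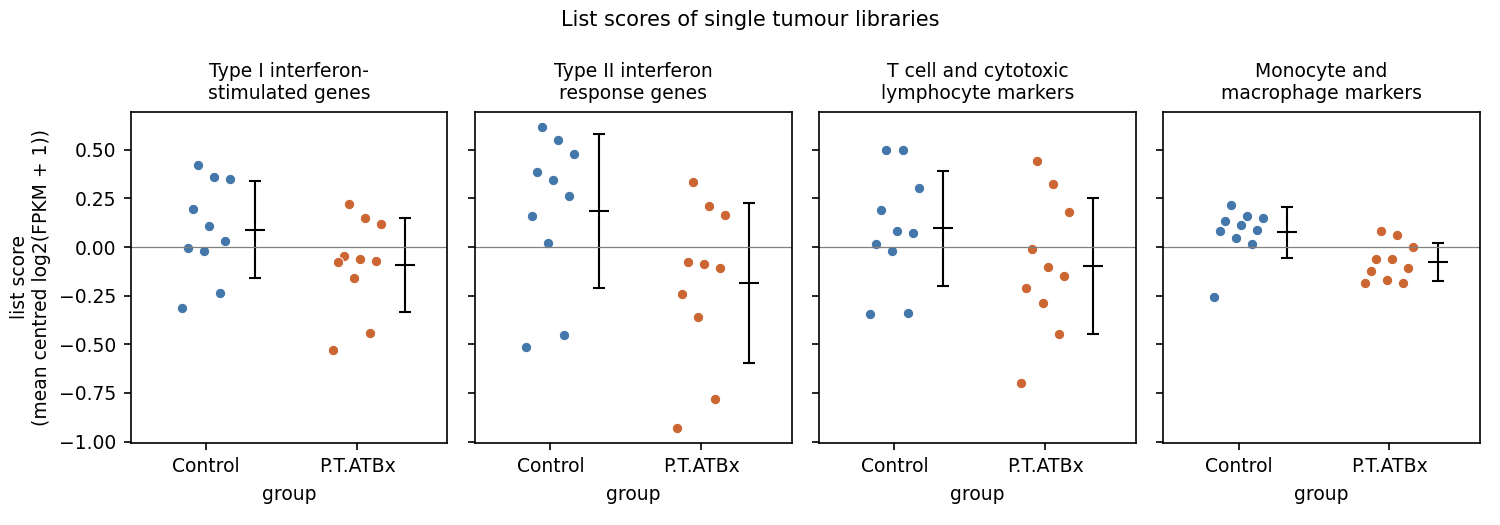
Each panel plots the score of 1 gene list (mean over members of gene-centred log2(FPKM + 1)) per tumour library in the Control and P.T.ATBx groups (n = 10 each), with the mean and SD beside the points. The groups overlap in all 4 panels; the type II interferon score averages 0.186 in Control and −0.186 in P.T.ATBx.

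Antigen presentation genes followed the interferon lists in direction. In the MHC class I list, 16 of 18 members were negative with a median log2 fold change of −0.17, and 0 passed over all genes or adjusted over the list alone. Tapbp (−0.17), H2-Q7 (−0.30), Tap1 (−0.28) and Tapbpl (−0.17) had the smallest p. It was lower by camera (adjusted p = 9.18e-05 and adjusted p = 0.626 with an estimated correlation). B2m, the common light chain, was at 4976 ± 594 FPKM in Control and 5017 ± 606 in P.T.ATBx (SD, n = 10 each), a log2 fold change of 0.01. In the MHC class II list 0 of 10 passed, 7 were negative, the median was −0.24, and camera made no call (adjusted p = 0.0716). H2-DMb1 (−0.27), H2-DMa (−0.26), H2-Eb1 (−0.34) and Ciita (−0.25) had the smallest p. Camera called the list lower with a filter at a mean FPKM of 1 (adjusted p = 0.035), on the TPM scale (adjusted p = 0.0423) and, with adjusted p from 0.00929 to 0.0423, without any 1 of Control 2 or 3 or P.T.ATBx 4, 6 or 7 (adjusted p = 0.638 with an estimated correlation in all libraries). Without P.T.ATBx 2 camera gave adjusted p = 0.249, and H2-DMb1, H2-DMa, H2-Eb1 and Ciita had −0.18, −0.17, −0.18 and −0.15.

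Lymphocyte markers mostly had negative values. Of 19 T cell and cytotoxic lymphocyte markers 18 were negative, with a median of −0.18, and 0 passed over all genes or adjusted over the list alone. Cd3d was at 4.16 ± 1.41 FPKM in Control and 2.93 ± 0.909 in P.T.ATBx (log2 fold change −0.38, adjusted p = 0.245, limma), Cd3g had −0.38, Nkg7 −0.30 and Cd8a −0.28 (adjusted p = 0.623, limma). On leaving out 1 library, Nkg7 ran from −0.37 (without P.T.ATBx 6) to −0.19 (without P.T.ATBx 2) and Cd8a from −0.38 (without P.T.ATBx 6) to −0.18 (without Control 4). Camera called the list lower (adjusted p = 0.0033 and adjusted p = 0.638 with an estimated correlation), and leaving out P.T.ATBx 2 ended that call (adjusted p = 0.0607). In the inhibitory checkpoint list 0 of 12 passed over all genes, and adjusted over the list alone 1 was lower, Pdcd1lg2, which encodes the ligand PD-L2 (2.69 ± 1.39 and 1.18 ± 0.479 FPKM, log2 fold change −0.71, SE 0.18, adjusted p = 0.0608 over all genes, limma). Pdcd1 had −0.35 and Btla 0.12, and camera made no call (adjusted p = 0.132) except without any 1 of Control 2 or 3 or P.T.ATBx 6 (adjusted p from 0.0275 to 0.0364, and adjusted p = 0.678 with an estimated correlation in all libraries). NK cell markers had 5 positive and 7 negative members, with a median of −0.02 where the mean (0.04) and camera (adjusted p = 0.747) pointed up. CD4 and regulatory T cell markers had 7 of 8 negative members (median −0.12, camera adjusted p = 0.0952, and from 0.0221 to 0.0454 without any 1 of Control 2 or 7 or P.T.ATBx 6 or 7, against adjusted p = 0.638 with an estimated correlation in all libraries). B cell markers had 3 tested members (median 0.15, camera adjusted p = 0.59). In these 3 lists 0 members passed over all genes or adjusted over the list alone.

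Among 20 monocyte and macrophage markers, Arg1 and the scavenger receptor gene Msr1 fell over all genes (Msr1 log2 fold change −0.30, SE 0.06, adjusted p = 0.0243, limma) and 18 did not pass. Adjusted over the list alone, 4 were lower and 3 higher, the higher ones including the lipid-sensing receptor gene Trem2 (0.20) and the lysosomal protein gene Cd68 (0.17). The list median was −0.06, camera made no call (adjusted p = 0.132), and fry's mixed test, which asks for change in either direction, gave adjusted p = 0.00551. All 10 P.T.ATBx libraries had a score below the Control median (difference −0.15, two-sided permutation p = 0.0104, adjusted p = 0.177). The score is a mean over the 20 members, 8 of them positive, so the large fall of Arg1 (−1.97) weighs heavily in it. Without Control 2 the score (adjusted p = 0.0087) and camera (adjusted p = 0.0186) passed, where camera had adjusted p = 0.647 with an estimated correlation in all libraries. Msr1 lost its call without P.T.ATBx 4 (adjusted p = 0.0575, limma), without P.T.ATBx 9 (adjusted p = 0.0509, limma), on the TPM scale (adjusted p = 0.127, limma) and without the 4 libraries that stand apart (adjusted p = 0.149, limma).

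Neutrophil markers had 9 of 10 negative members, a median of −0.26 and 0 past the threshold over all genes. The 2 genes lower adjusted over the list alone were Retnlg (7.57 ± 3.82 and 3.04 ± 1.39 FPKM, log2 fold change −1.04, SE 0.27, adjusted p = 0.0722 over all genes, limma) and the cytokine gene Il1b (−0.39, adjusted p = 0.137 over all genes, limma). Mmp9 (−0.25) and Hdc (−0.21, from −0.26 without Control 6 to −0.13 without Control 10) followed. S100a8 was at 9.51 ± 9.67 and 4.78 ± 1.39 FPKM (adjusted p = 0.798, limma). Camera called the list lower (adjusted p = 0.0033 and adjusted p = 0.573 with an estimated correlation), while 5 of 10 P.T.ATBx libraries scored below the Control median and 5 above (score difference −0.295, two-sided permutation p = 0.109, adjusted p = 0.337). NF-kB cytokines and targets had 17 of 19 negative members and a median of −0.19, with 0 past the threshold over all genes. Adjusted over the list alone 4 were lower, Ccl7 (−0.33), Il1b, Lif (−0.19) and Tnf (−0.38). All 10 P.T.ATBx libraries scored below the Control median. The score difference was −0.176 (two-sided permutation p = 0.0406, adjusted p = 0.196), and camera called the list lower (adjusted p = 0.00017 and adjusted p = 0.573 with an estimated correlation). Il1b stands in both lists.

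Dendritic cell markers had 10 of 12 negative members (median −0.14) and 0 past the threshold over all genes. Adjusted over the list alone the chemokine gene Ccl22 was lower (−0.34) and the integrin gene Itgae higher (0.25). Cd209a had −0.23 and Clec9a −0.17, and camera made no call (adjusted p = 0.103). Antimicrobial effectors had 9 of 11 negative members (median −0.32, camera adjusted p = 0.0345 and adjusted p = 0.573 with an estimated correlation), 0 of them past the threshold over all genes or adjusted over the list alone. That call ended with a pseudocount of 0.1 (adjusted p = 0.0609), arrayWeights (adjusted p = 0.186), neighbouring tissue scores as covariates (adjusted p = 0.171) or the ribosomal protein covariate (adjusted p = 0.0523). It also ended without the 4 libraries that stand apart (adjusted p = 0.24) and, with adjusted p from 0.0538 to 0.191, without any 1 of Control 1, 5, 9 or 10 or P.T.ATBx 2 or 4. Bacterial sensing genes had 14 of 20 negative members (median −0.05, camera adjusted p = 0.0667), with 0 past the threshold over all genes and 1 lower adjusted over the list alone. Camera called that list lower with a filter at a mean FPKM of 1 (adjusted p = 0.0409), with neighbouring tissue scores as covariates (adjusted p = 0.0426), and without any 1 of Control 2, 3 or 7 or P.T.ATBx 5, 6 or 7 (adjusted p from 0.00579 to 0.0454, and adjusted p = 0.638 with an estimated correlation in all libraries). Mast cell, basophil and eosinophil markers had a median of −0.02 over 7 members with 0 past the threshold (camera adjusted p = 0.566).

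Of 20 cell cycle genes 18 were negative, with a median log2 fold change of −0.08, and 0 passed over all genes. Adjusted over the list alone 3 were lower, the mitotic kinase genes Aurkb (35.0 ± 2.45 and 31.2 ± 1.63 FPKM, −0.16) and Aurka (−0.16) and the replication helicase gene Mcm3 (−0.21). Top2a had −0.17 (adjusted p = 0.209, limma). Camera called the list lower (adjusted p = 9.01e-05 and adjusted p = 0.573 with an estimated correlation).

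Immediate early and handling stress genes were the 1 list called higher by camera (adjusted p = 0.0149 and adjusted p = 0.573 with an estimated correlation). Of 15 members 3 rose over all genes, Fosb, the transcription factor gene Egr1 (2.92 ± 0.444 and 4.01 ± 0.673 FPKM, log2 fold change 0.35, adjusted p = 0.0325, limma) and the chaperone gene Hspa1a (0.41, adjusted p = 0.0345, limma), and 12 did not pass. Adjusted over the list alone 6 were higher, the phosphatase gene Dusp1 (0.29) among them, and 1 was lower. The call by camera ended without Control 1 (adjusted p = 0.0518) and with a filter at a mean FPKM of 1 (adjusted p = 0.0593). Egr1 lost its call on the TPM scale (adjusted p = 0.143, limma), with neighbouring tissue scores as covariates (adjusted p = 0.068, limma) and in 6 fits without 1 library (adjusted p from 0.052 to 0.0597, limma). Hspa1a lost its call on the TPM scale (adjusted p = 0.0551, limma), with those covariates (adjusted p = 0.066, limma), without the 4 libraries that stand apart (adjusted p = 0.127, limma) and in 9 fits without 1 library (adjusted p from 0.0538 to 0.0717, limma).

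In the hypoxia and glycolysis list, 1 of 18 members was lower over all genes and adjusted over the list alone, the oxygen-sensing prolyl hydroxylase gene Egln3 (log2 fold change −0.44, SE 0.07, adjusted p = 0.00125, limma). Ddit4 had 0.40 (adjusted p = 0.193, limma), Ldha −0.16 and Aldoa −0.16. The list had a median of −0.09 and was lower by camera (adjusted p = 0.0325 and adjusted p = 0.638 with an estimated correlation). That call ended with the ribosomal protein covariate (adjusted p = 0.0618) and, with adjusted p from 0.0578 to 0.144, without any 1 of Control 2, 7 or 10 or P.T.ATBx 3 or 5. Targets of the integrated stress response had 13 of 16 negative members, with 0 past the threshold over all genes and 2 lower adjusted over the list alone (median −0.06, camera adjusted p = 0.0149 and adjusted p = 0.638 with an estimated correlation). That call ended without a filter on low values (adjusted p = 0.0704) and without any 1 of Control 7 or 10 or P.T.ATBx 5, with adjusted p from 0.0576 to 0.102.

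Among 18 fibroblast and matrix genes, the matrix proteoglycan gene Dcn fell from 671 ± 40.1 to 543 ± 39.5 FPKM (SD, n = 10 each, log2 fold change −0.31, SE 0.05, adjusted p = 0.00125, limma) and 17 did not pass. Adjusted over the list alone 2 were lower, Dcn and Pi16 (−0.92, adjusted p = 0.0854 over all genes, limma). Thy1 had −0.23 and Pdgfrb 0.19. The list had a median of −0.07 and was lower by camera (adjusted p = 0.0259 and adjusted p = 0.573 with an estimated correlation). The call ended with arrayWeights (adjusted p = 0.077), with neighbouring tissue scores as covariates (adjusted p = 0.107) and with the ribosomal protein covariate (adjusted p = 0.0571). It also ended without Control 9 (adjusted p = 0.0695), without P.T.ATBx 1 (adjusted p = 0.0901) and without the 4 libraries that stand apart (adjusted p = 0.237).

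Markers of neighbouring tissue varied widely within both groups, and their camera tests depended on single libraries. Adipocyte genes were all negative (11 members, median −0.40, camera adjusted p = 0.0716), with scores of 0.210 ± 1.46 in Control and −0.210 ± 0.863 in P.T.ATBx (SD, n = 10 each). Skeletal muscle genes were all positive (11 members, median 0.34, camera adjusted p = 0.0713), with scores of −0.181 ± 0.948 and 0.181 ± 0.683. Keratinocyte genes (8 members, median −0.18, camera adjusted p = 0.103) and erythroid genes (3 members, median −0.35, camera adjusted p = 0.143) were not called. Neither were epithelial tumour cell genes (10 members, median −0.24, camera adjusted p = 0.177) and endothelial markers (13 members, median −0.02, camera adjusted p = 0.495). In these 6 lists 0 members passed over all genes, and adjusted over the list alone 1 epithelial member was higher. The epithelial score was highest in Control 3 (1.63) and lowest in Control 8 (−1.31), as was the adipocyte score (2.81 and −1.89). The epithelial list therefore need not measure tumour cell content. Camera called muscle genes higher with a pseudocount of 0.1 (adjusted p = 0.00919), without a filter (adjusted p = 0.0265), on the TPM scale (adjusted p = 0.0218) and in 4 fits without 1 library (adjusted p from 2.32e-05, without Control 10, to 0.0257). These calls used the preset correlation, and with an estimated correlation in all libraries, 0.924 between muscle genes and 0.921 between adipocyte genes, camera gave both lists adjusted p = 0.678, keratinocyte genes adjusted p = 0.638 and epithelial genes adjusted p = 0.697. At the preset value it called adipocyte genes lower on the TPM scale (adjusted p = 0.0382) and in 8 fits without 1 library (adjusted p from 0.00541 to 0.0465), keratinocyte genes lower in 5 such fits (adjusted p from 0.0315 to 0.0493) and epithelial genes lower without Control 8 (adjusted p = 0.0213).

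Over all 29 lists, camera called 12, of which 11 were lower and 1 higher, and 0 with an estimated correlation, where the lowest adjusted p was 0.573. Fry's directional test called 0 and its mixed test 4, and the score tests called 0 after adjustment and 6 at an unadjusted p under 0.05.

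**Figure D4:**
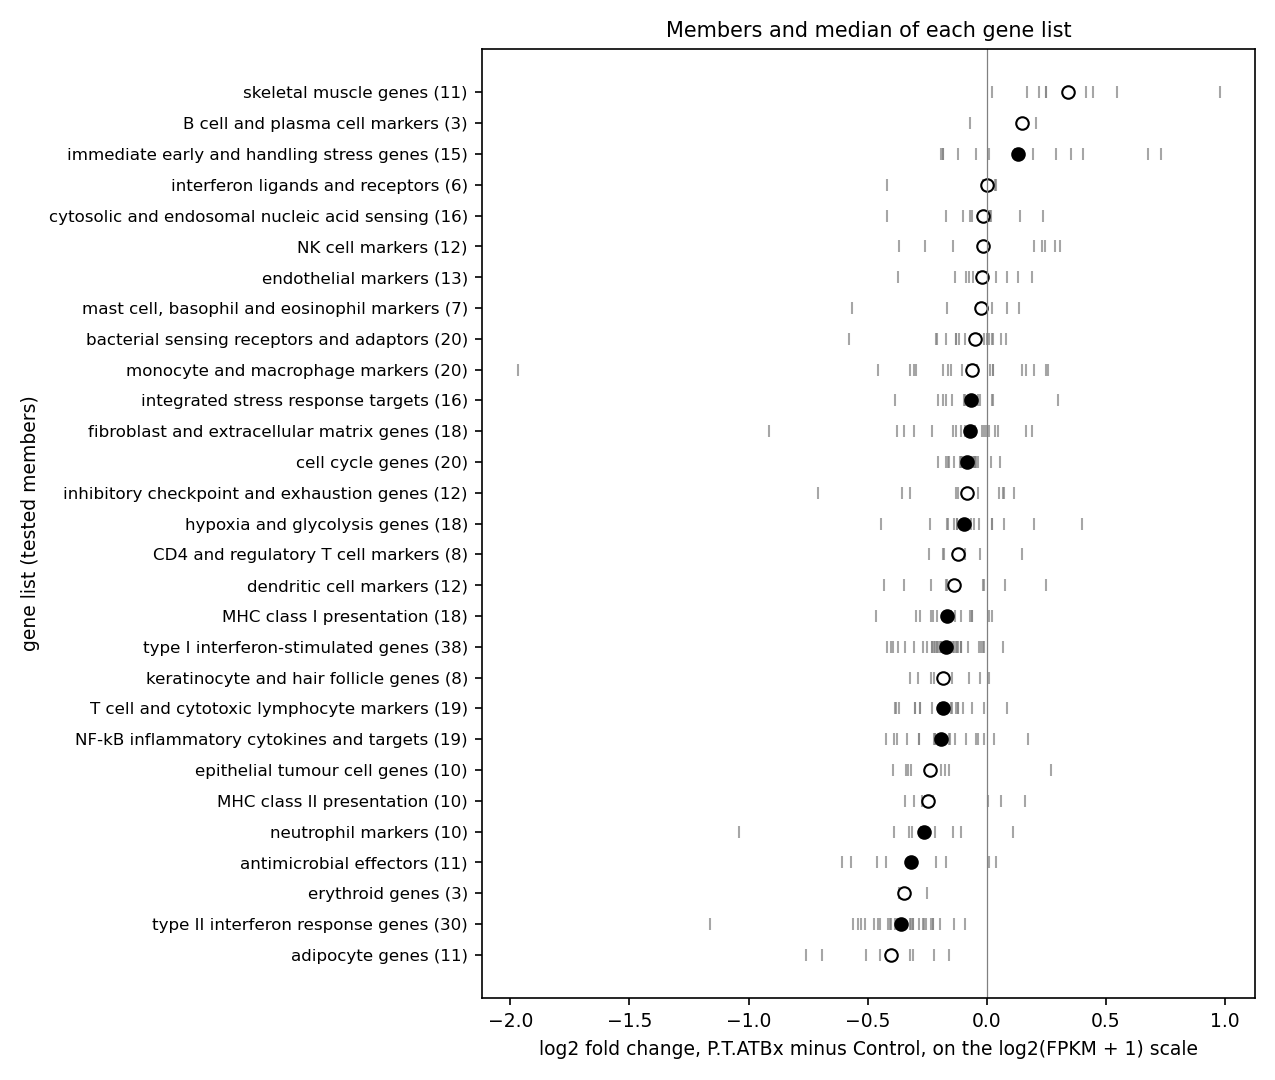
Each row is 1 gene list, with the number of tested members in parentheses; ticks are the log2 fold changes of the members (P.T.ATBx minus Control, log2(FPKM + 1) scale), and the circle is their median, filled where camera with a preset correlation gave an adjusted p under 0.05. All 30 type II interferon members lie below 0, with Ido1 at −1.16, and Arg1, at −1.97, lies far to the left in the monocyte and macrophage list.

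Across the 10 libraries of a group, both interferon scores followed the MHC class I score in Control and in P.T.ATBx. The T cell score was followed by both in P.T.ATBx and by type II in Control, and the monocyte and macrophage score by both in P.T.ATBx. Of 16 relations computed, 9 passed at a Benjamini-Hochberg adjusted p under 0.05, 3 in Control and 6 in P.T.ATBx, and 3 passed without the 2 libraries farthest from the median. Those 3 were type I with MHC class I in Control (r = 0.920, and r = 0.844 without the 2, adjusted p = 0.0118) and type II with T cell and MHC class I scores in P.T.ATBx (adjusted p = 0.00464 each). The type I relations in P.T.ATBx with MHC class I (r = 0.949) and T cell scores (r = 0.900) had adjusted p = 0.0655 and 0.0678 without the 2. In Control the type I and T cell scores had r = 0.647 (permutation p = 0.0434, adjusted p = 0.0695). In P.T.ATBx the type II interferon score rose with the T cell score (n = 10, Pearson r = 0.960, permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 8e-05). Spearman's rho was 0.976 (permutation p = 2e-05, adjusted p = 0.00016), and r was 0.959 without the 2 libraries farthest from the median. In Control the same relation had r = 0.709 (n = 10, permutation p = 0.0224, adjusted p = 0.0399) and rho = 0.467 (permutation p = 0.181, adjusted p = 0.29). There r was 0.0394 without the 2 farthest libraries, so it rests on them. The difference between the groups was not tested. The type II score followed the MHC class I score in Control (r = 0.953, permutation p = 0.0003, adjusted p = 0.00096, rho = 0.903, permutation p = 0.00093, adjusted p = 0.00372, n = 10). It did so in P.T.ATBx (r = 0.979, permutation p = 1e-05, adjusted p = 8e-05, rho = 0.976, permutation p = 2e-05, adjusted p = 0.00016, n = 10), and without the 2 farthest libraries r was 0.740 (adjusted p = 0.0759) and 0.958. In P.T.ATBx the monocyte and macrophage score rose with the type I score (n = 10, r = 0.810, permutation p = 0.00484, adjusted p = 0.00968, rho = 0.830, permutation p = 0.00468, adjusted p = 0.0125). It rose with the type II score as well (n = 10, r = 0.834, permutation p = 0.00286, adjusted p = 0.00654, rho = 0.806, permutation p = 0.00715, adjusted p = 0.0163). Without the 2 farthest libraries these r were 0.747 (adjusted p = 0.0759) and 0.798 (adjusted p = 0.0655). The same relations had r = 0.439 (adjusted p = 0.248) and r = 0.582 (adjusted p = 0.116) in Control. Dendritic cell scores did not follow the type II score in Control (n = 10, r = 0.520, permutation p = 0.131, adjusted p = 0.175, rho = 0.394, permutation p = 0.262, adjusted p = 0.38). Nor did they in P.T.ATBx (n = 10, r = 0.223, permutation p = 0.534, adjusted p = 0.534, rho = 0.0424, permutation p = 0.918, adjusted p = 0.918). Without the 2 farthest libraries these r were −0.167 and −0.166.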

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

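In 136 sets of 10 libraries, each a library measure, list score or named gene in 1 group, 8 had a highest or lowest library farther from the next than Dixon's 95% critical value for the gap over the range, where chance gives about 1 in 20. Of the tests of the interferon lists, the one without the 4 libraries was chosen after the result was seen, as was the use of the planned Ptprc covariate as a test of leukocyte content and the test of the granzyme neighbours.

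Control 1 had a summed FPKM of 752800 against a Control median of 581100 and a mean log2 level of ribosomal protein genes of 9.45 against 9.04. Control 2 had a monocyte and macrophage score of −0.257 against 0.102. Control 10 had a skeletal muscle score of 2.20 against −0.543. P.T.ATBx 2 had a B cell score of −0.493 against a group median of 0.0791 and an H19 level of 6.69 on the log2(FPKM + 1) scale against 6.01. P.T.ATBx 8 had an integrated stress response score of 0.326 against −0.0355. Control 9 had a Ubl4a level of 2.01e-07 on the log2(FPKM + 1) scale, almost 0, against 1.33.

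The count of 59 higher and 49 lower genes was reached by 2 of 100 splits of the 20 libraries into 10 and 10, the real split included. The highest other split gave 146 genes, more than the 108 of the real split. Such a count was rare among the splits drawn, but chance is not excluded. That other split put the 4 libraries that stand apart in composition on 1 side, with 7 P.T.ATBx and 3 Control libraries there and a mean log2 ribosomal protein level of 9.17 against 9.00, so a structure of the libraries other than treatment can also give such a count. The same side had lower interferon scores, −0.117 against 0.117 for type I (permutation p = 0.0371) and −0.193 against 0.193 for type II (permutation p = 0.0448), gaps as large as those between the treatment groups. This split was picked for its gene count, so these p-values are not free of selection. With 7 P.T.ATBx libraries on that side, treatment could give part of the gaps. The 12 lists called by camera were reached by 35 of 100 splits, with 21 lists in the highest other split, so chance cannot be excluded for that count.

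The interferon lists were lower by camera, calls lost with an estimated correlation (adjusted p = 0.626 for type I and 0.573 for type II), and their scores did not pass. Ptprc, the common leukocyte antigen, was at 44.6 ± 7.61 FPKM in Control and 43.8 ± 9.52 in P.T.ATBx (permutation p = 0.783), which gives no sign of fewer leukocytes. With Ptprc as a covariate 88.3% of the type II list difference remained (−0.329 in place of −0.373, permutation p = 0.00131). A covariate so alike between the groups could remove little of the difference, so that fit cannot decide the question. The 4 libraries that stand apart are argued against as the cause, since without them the type II difference was 110% of its size (permutation p = 0.0478). P.T.ATBx 2 is not among them, and without it alone the type II difference was −0.29 and the type I difference −0.132, against −0.373 and −0.181 in all libraries. A variation in composition that runs through more libraries stays open, as the other split above had type II scores as far apart. With the score of T cell markers outside the list as a covariate, 45.6% remained (−0.170, permutation p = 0.11). A lower T cell content may account for part of the difference, but was not itself shown. The T cell score differed by −0.192 between the groups (two-sided permutation p = 0.2). The type II and T cell scores ran together in P.T.ATBx (r = 0.960), so T cells and interferon responses could also fall together for another reason. Direct action of the treatment on interferon signalling stays open and was not tested.

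Gzmd, Gzme and Gzmg fell while Gzma and Gzmb did not pass. A shift of all the lost reads to near-identical neighbours that otherwise stayed the same is argued against. The summed Gzmc and Gzmf FPKM differed by −25.4 (95% bootstrap interval −64.3 to 15.9), with an upper bound below the 21 FPKM that the 3 genes lost. A partial shift is not excluded, nor is a gain hidden by a separate fall of the neighbours. Gzmf itself went from 20.4 FPKM in Control to 8.52 in P.T.ATBx. With the T cell score as a covariate 95% of the mean log2 fold change of the 3 genes remained and each stayed past the threshold. That score differed by only −0.192 between the groups (two-sided permutation p = 0.2), so it could remove little of such falls. An even loss of all cells with these markers is argued against as the whole cause. Fewer cells of a subset that the score does not mark was not tested. A change in which granzymes the cells of these tumours transcribe is a candidate explanation, a hypothesis found on these data that was not tested.

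The 59 genes higher after P.T.ATBx could reflect trends with transcript length and GC content, but 91.5% of them, 54 genes, stayed past the threshold after each library's trend was removed. Their median transcript was 4.02 kb, against 2.66 kb for lower and 3.31 kb for other genes. Their median genomic span was 28.9 kb, against 20.7 kb and 22.2 kb, and a trend with genomic span was not tested. A lower share of leukocytes was not seen by Ptprc, at 44.6 ± 7.61 FPKM in Control and 43.8 ± 9.52 in P.T.ATBx (SD, n = 10 each, permutation p = 0.783). With Ptprc as a covariate 101% of the median log2 fold change of the 59 genes remained (0.33 in both fits). A covariate so alike between the groups could hardly have changed it. Library numbers run on from Control to P.T.ATBx in the labels, so any effect of processing order cannot be told apart from treatment.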

How the results depend on the processing

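Of the 25 named genes past the threshold, 14 kept their call under every alternative run for them: Arsi, Dcn, Egln3, Epha3, F3, Fosb, Gpnmb, Gzmd, Gzme, Gzmg, Igf2, Lipg, Syngr1 and Tmem26. The 25 genes kept their direction under all alternatives, with 71 of 798 values no longer past the threshold. The fits without the 4 libraries, with ribosomal protein genes or, for gene counts, Ptprc as a covariate and with length and GC trends removed were chosen after seeing the data. The cause of the changes below was not tested, except that fewer libraries leave less power. Depth is known only as a relative value, and genes of a few reads rest on coarse steps. Ubl4a was listed at 1.391e-07 FPKM in Control 9, against 1.033 in Control 1, its next lowest library. So small a value is not a step of whole reads, and how it arose was not tested.

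Higher and lower genes numbered 59 and 49 as reported. They were 20 and 29 on the TPM scale, 154 and 152 with arrayWeights, 31 higher without the 4 libraries, 198 and 141 with the ribosomal protein covariate (all 59 and 49 shared), 115 and 106 with Ptprc as a covariate (all shared), and 117 and 83 with length and GC trends removed (100 shared). Leaving out 1 library gave 38 (without P.T.ATBx 4) to 104 (without Control 1) higher and 31 (without P.T.ATBx 4) to 89 (without Control 1) lower, with 78 lower without Control 2. The numbers of the replicates showed no clear pairing of the libraries: same-numbered deviations correlated from −0.315 to 0.393, 5 of 10 pairs above 0.1, and 3 libraries correlated best with their own number. Pairing was not tested, so it is not excluded. With the number as a block there were 65 higher and 59 lower genes, 81 of them shared. With it 6 of the 25 genes, Arg1 (adjusted p = 0.0634, limma), Islr (0.0565), Msr1 (0.0973), Nov (0.101), Prl2c2 (0.0598) and Ubl4a (0.0602), did not pass, and camera called MHC class II (0.0438) and bacterial sensing genes (0.0402) lower.

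With an estimated correlation camera called 0 lists, with adjusted p = 0.626 for type I and 0.573 for type II interferon genes. Both lists, MHC class I, NF-kB, neutrophil and cell cycle genes kept their camera calls under the other alternatives. The type II score passed with Ptprc as a covariate (difference −0.329, adjusted p = 0.0168, adjusted p ranged from 0.0168 to 0.477 over its alternatives). Score tests called 0 to 2 lists on leaving out 1 library, with NF-kB (adjusted p = 0.0222) and monocyte and macrophage markers (adjusted p = 0.0087) past it without Control 2. Without the 2 farthest libraries 3 of the 9 relations passed.

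Nov lost its call in 17 fits, with adjusted p (limma) from 0.05 to 0.149, among them those without any 1 of Control 2, 6, 7, 9 or 10 or P.T.ATBx 1, 3, 4, 5, 9 or 10 (0.0575 to 0.0918). Itga7 lost it in 11, among them those without any 1 of Control 4, 5 or 6 or P.T.ATBx 3, 4, 5, 7, 9 or 10 (0.05 to 0.0664). Of the named genes not past the threshold 17, and of the lists not called by camera 9, passed in the reported direction under some alternative, in 39 of 1852 and 47 of 561 values.

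Directions that turned belonged to lists and 1 gene not past the threshold. By camera's adjusted p these were, without a filter, interferon ligands (0.307) and B cells (0.959). With arrayWeights they were mast cells (0.738), endothelium (0.877), adipocytes (0.93) and epithelium (0.91). With tissue covariates they were muscle (0.921), keratinocytes (0.986), adipocytes (0.959) and epithelium (0.242, score 0.108). Without the 4 libraries they were NK cells (0.586, score −0.0468), mast cells (0.83), endothelium (0.586, score 0.0227), adipocytes (0.586, score 0.115), epithelium (0.72, score 0.0677) and B2m (log2 fold change −0.0444). On leaving out 1 library, adjusted p ran from 0.173 to 0.985 for NK cells (scores −0.0598 to 0.125), 0.171 to 0.872 for endothelium (scores −0.0498 to 0.00861), 0.393 to 0.997 for interferon ligands and 0.195 to 0.964 for mast cells, and B2m from −0.0302 to 0.055.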

Other observations

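Genes in the next 2 paragraphs were chosen after their values were seen. Of the 59 genes higher after P.T.ATBx, 7 were cadherins or protocadherins, which encode cell adhesion proteins: Pcdh9 (log2 fold change 0.46, adjusted p = 0.00118, limma), Pcdh10 (0.39, adjusted p = 0.00583, limma), Cdh10 (0.33), Cdh18 (0.32), Cdh19 (0.33), Pcdhb16 (0.25) and Pcdhb17 (0.31). They were low, from 0.553 ± 0.175 FPKM for Cdh10 to 4.98 ± 0.821 for Cdh19 in Control (SD, n = 10). Of 49 tested Cdh and Pcdh genes 7 were higher, 0 lower and 42 not past the threshold, in a family picked because it stood out. Of the 49, 24 belong to the clustered protocadherins, whose copies share sequence.

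The receptor genes Epha7 (0.26), Grik2 (9.39 ± 1.17 and 12.2 ± 1.27 FPKM, 0.35) and Gria4 (0.35) rose, as did the adhesion gene Slitrk5 (0.37) and the transcription factor gene Mef2c (0.47, adjusted p = 0.0222, limma). The same held for the lysosomal protease gene Ctsd (475 ± 30.4 and 568 ± 62.7 FPKM, 0.25, adjusted p = 0.0321, limma), the kinase gene Sgk1 (0.24, adjusted p = 0.00118, limma), the myeloid receptor gene Cd33 (0.45) and the cold-inducible RNA-binding protein gene Cirbp (0.35). Among lower genes were Ly6c1 (48.6 ± 9.69 and 34.0 ± 5.65 FPKM, −0.50, adjusted p = 0.028, limma), Plac8 (150 ± 27.1 and 112 ± 15.4 FPKM, −0.41), the complement properdin gene Cfp (−0.46), the water channel gene Aqp1 (−0.44), the phosphatase gene Acpp (80.7 ± 7.09 and 58.6 ± 4.65 FPKM, −0.45, adjusted p = 8.22e-05, limma) and the apolipoprotein gene Apod (−0.49, adjusted p = 0.000609, limma). Values are SD with n = 10 per group. In Acpp all P.T.ATBx libraries lay below all Control libraries.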
